A study of Mus musculus with 9 samples.

How the data were processed

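Liver total RNA of mice, C57BL/6 and 5 weeks old at the start per the labels' protocols (the strain entry of the labels reads C56BL/6J), was hybridised as biotin-labelled sense cDNA to a whole-transcript GeneChip, a microarray with probes along the whole transcript. The livers were collected after an overnight fast per the labels' protocols. The sex of the mice is not given in the sources used here, and no sex was inferred. There were 9 arrays, 3 for each of the regular diet, the high-fat diet and the high-fat diet with ginseng flower bud extract, and no array was left out.

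The deposited values are log2 expression values per probe set that the authors made by robust multi-array average (RMA) with the R package oligo, per the submitters' processing notes, which give no versions. RMA subtracts background, quantile-normalizes the arrays and summarises the probes of a probe set, so a shift shared by most genes of an array would have been removed, and dim probe sets keep a value near background. The median of the gene means was 4.74, and no detection calls, scan dates or batch information were used here. The genome build behind the probe sets is not given in the sources used here. No value was missing, and no further transformation or normalization was applied.

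Of the probe sets on the array, 23521 had 1 gene symbol in its annotation table, 1814 had several and 16010 had none, and only the first kind was tested in the comparisons. For the 1082 genes with more than 1 probe set, the probe set with the highest mean stood for the gene, which left 22180 genes. The symbols were checked by gene identifier against the RefSeq annotation of the mouse assembly GRCm38.p6, used for names only. They were equal for 23328 probe sets, 193 had no match and 0 differed.

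Groups were compared with limma 3.58.1 in R 4.3.3. A linear model with a mean for each group was fitted to all 9 arrays, which left 6 residual degrees of freedom, and the variances were moderated with 3.28 prior degrees of freedom. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, two-sided. With 3 arrays against 3, an exact permutation test of a single gene could not go below p = 0.1, so no such test was used for calls. The 3 comparisons were the high-fat diet against the regular diet, extract on the high-fat diet against the high-fat diet, and extract on the high-fat diet against the regular diet. A moderated F test compared all 3 groups.

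Gene lists for liver metabolism, inflammation, stress, the clock, sex-biased expression and the cell types that a liver sample could hold, 33 in all with 557 symbols of which 497 were measured, were tested with limma's camera at its preset correlation of 0.01. The 32 lists with at least 5 measured genes were adjusted together within each comparison. Camera with the correlation estimated for each list, and fry, which asks whether the genes of a list move on balance in one direction without comparing them with other genes, were run as alternatives. The covariance across genes of the diet and extract effects was set beside 100 simulated sets of unchanged groups with the same shared arrays. Sets of 100 simulations with the measured diet effect and no extract effect were chosen after seeing the data. They served the version with separate high-fat diet arrays and a further test of the covariance with shared arrays. The simulated noise mixed the measured residuals at random, which may overstate how strongly genes move together.

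The genes named in each comparison were the 10 with the largest rise and the 10 with the largest fall among those that passed with no overlap between the groups, without predicted genes and most non-coding RNAs. Where fewer than 5 passed in a direction, the 5 with the smallest p were named instead. Up to 4 genes of each list with the smallest p, and Fasn, Scd1, Srebf1, Pparg, Cd36, Cidec, Cpt1a, Tnf, Il6, Ccl2, Pck1, Irs2 and Cyp7a1 in every comparison, could be named as well. The comparisons, tests, lists, naming rule and all alternatives but 1 were chosen before the data were examined. The alternatives were moderation with a variance trend and robust fitting, the genes above the median brightness, the mean of a gene's probe sets, quantile normalization once more, a shift of each array to the same median, array weights, the replicate number as a block, an adjusted p under 0.10, a fold change of at least 1.5, a fit of only the 6 arrays compared, and leaving out each array in turn. The alternative chosen after seeing the data used separate high-fat diet arrays for the diet and extract effects.

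The procedure was tested on simulated data of the same design with 22180 genes, 5 simulations and 200 changed genes in each. It recovered 45.5% of genes with a log2 change of 0.5, 87.0% at 1 and 98.8% at 2, and 40 of 816 calls (4.90%) were false. It made 0 calls where no gene was changed. A list shifted by 0.5 was found in 5 of 5 simulations and 0 of 155 unshifted lists were called, although the simulated genes were independent and real genes are not. A planted covariance of -0.0200 was recovered as -0.0201 after the part expected from the shared high-fat diet arrays was taken off. The covariance of the diet and extract effects with shared arrays is given below without that correction, beside the simulated groups.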

Results

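Liver RNA was measured on whole-transcript microarrays in 9 mouse samples that form 3 groups of 3 arrays each. One group was fed a regular diet, another a high-fat diet, and the last a high-fat diet together with an extract of ginseng flower buds, the flower buds of the ginseng plant. The extract was given by mouth at 500 mg/kg once a day for 12 weeks, and the other mice received vehicle. The title of the series names fatty liver, liver inflammation and insulin resistance as the traits of interest. Array medians ran from 4.34 to 4.38 on the log2 scale, and 22180 genes were tested. Array profiles correlated across genes at 0.991 to 0.994 within groups and at 0.987 to 0.993 between groups. The first principal component held 29.2% of the variance and placed the 3 regular-diet arrays between -26.63 and -10.79 and the other 6 arrays between 5.66 and 11.71. The labels do not state that each array is a separate mouse, so the p-values measure the spread between these samples, and the number of arrays limits the precision. Changes are given as log2 fold changes ± standard error with 3 arrays per group, and adjusted p-values come from limma across all genes tested.

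The high-fat diet was compared with the regular diet to describe the liver on the diet alone. Genes of cholesterol synthesis, acute-phase genes and interferon-induced genes were higher on the high-fat diet, and genes of fatty acid oxidation and gluconeogenesis were lower. These 5 lists were shifted with the preset correlation, but not with an estimated correlation (adjusted p from 0.206 to 0.308), and 12 of 19, 7 of 17, 2 of 18, 4 of 25 and 1 of 11 of their genes passed singly. Sqle, which encodes squalene epoxidase of the sterol pathway, rose 6.88-fold (2.78 ± 0.23, adjusted p = 0.00276), and Lcn2, which encodes the acute-phase protein lipocalin 2, rose 6.65-fold (2.73 ± 0.35, adjusted p = 0.0131). Lepr, the leptin receptor gene, fell 17.3-fold (-4.12 ± 0.65, adjusted p = 0.0223), and Ehhadh, which encodes an enzyme of peroxisomal beta-oxidation, fell 3.65-fold (-1.87 ± 0.20, adjusted p = 0.00687). The log2 fold change of Lepr was -5.05 without regular-diet replicate 1 and -3.51 without regular-diet replicate 3, where it no longer passed (adjusted p = 0.0635). Signal under the median gene mean of 4.74 is not told from background here, and the mean lay below it on the regular diet for Sqle (4.49), Themis (4.12), Gbp3 (4.53), Cyp2b9 (4.01) and Ccl2 (4.30) and on the high-fat diet for Lepr (3.97). Apart from the spread between arrays, the sizes of the diet differences given for Sqle, Themis, Gbp3 and Lepr are therefore lower bounds. Cyp2b9 and Ccl2 did not pass, so their differences are not read as bounds. Tnf and Il6 lay below that level in all 3 groups, as did Ccl2 with extract (4.58), and a difference between groups that both lie below it is not told from background. In all, 297 genes changed, of which 182 rose and 115 fell, 66 of them by more than 2-fold. The 3 arrays of one group lay entirely above or below the 3 of the other for all 297 of these genes, and for 15.8% of all genes tested, where chance gives 10%. The count was 58 without regular-diet replicate 2, 117 without regular-diet replicate 3, and 131, 117 and 63 without high-fat diet replicates 1, 2 and 3. It was 153 without extract replicate 1, 153 without extract replicate 2, 452 without regular-diet replicate 1, and 15 when only the 6 arrays compared were fitted.

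Gbp10, Msmo1, Themis, Thrsp, Lgals1, Slc22a7, Nsdhl and Ces1g also rose, with log2 fold changes from 2.03 to 2.67, a lower bound for Themis. Of these, Msmo1 and Nsdhl encode enzymes of sterol synthesis, Thrsp a protein of lipid synthesis in liver, Lgals1 galectin 1, Slc22a7 an organic anion transporter and Themis a protein of T cell development. Gbp10 and Ces1g belong to families with near-identical members, so the assignment of their signal to a single gene is uncertain. The naming rule passes over small nucleolar RNAs with Snora or Snord symbols, such as Snora73b (-1.50 ± 0.21) and Snora73a (-1.48 ± 0.22). Among the genes it admits, the other largest falls were Got1 (-2.03 ± 0.36, adjusted p = 0.034), Igfbp2 (-1.98 ± 0.32, adjusted p = 0.0243), Acot1, the small nucleolar RNA Rnu3a, Csad, Cth, Csrp2 and Tmem86a. The last 6 lay between -1.77 and -1.10. Csad and Cth encode enzymes of taurine and cysteine synthesis, and Got1 encodes the cytosolic aspartate aminotransferase. Regular-diet replicate 1 stood closest to the high-fat diet arrays for Lepr, at 6.23 against 8.73 and 9.30 in the other regular-diet arrays and 3.77 to 4.26 in the high-fat diet arrays. The naming rule took 148 genes for this comparison, of which 44 passed. Of those, 13 passed without any 1 array: Sqle, Msmo1, Cyp51, Steap4, Saa4, Cxcl1, Lgals1, Themis, Fitm1, Ehhadh, Acot1, Plin5 and Fabp2.

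Of the 19 measured genes of cholesterol synthesis, 12 rose, none fell and all 19 were higher, with a median of 0.87. Adjusted over the list alone, 17 rose. The list was shifted upward (adjusted p = 4.30e-24 with the preset correlation, and adjusted p = 0.206 with an estimated correlation). Cyp51, which encodes lanosterol demethylase, rose by 1.96 ± 0.25 beside Sqle, Msmo1 and Nsdhl. Of the 25 measured genes of fatty acid oxidation and PPAR-alpha targets, 4 fell and 23 were lower, with a median of -0.35, and 12 fell when adjusted over the list alone (adjusted p = 5.66e-12, and adjusted p = 0.236 with an estimated correlation). Cpt1a, which encodes the liver enzyme of fatty acid entry into mitochondria, stood at -0.36 ± 0.13 (adjusted p = 0.274). The 4 were Ehhadh, Acot1, Cyp4a14 (-0.98 ± 0.19) and Hadha (-0.49 ± 0.07), of which Acot1 and Cyp4a14 have near-identical paralogs. Of the 11 measured genes of gluconeogenesis, Got1 fell and 10 were lower, with a median of -0.43, and 4 fell when adjusted over the list alone (adjusted p = 2.32e-05, and adjusted p = 0.308 with an estimated correlation). Pck1, the phosphoenolpyruvate carboxykinase gene, had a log2 fold change of -0.89 ± 0.26 (adjusted p = 0.151) and Fbp1 of -0.43 ± 0.10 (adjusted p = 0.0863). Pck1 passed without extract replicate 3 (-0.89, adjusted p = 0.0471) and Fbp1 without regular-diet replicate 1 (-0.51, adjusted p = 0.0481). In a set chosen after the values were seen, 7 of 7 measured fasting-induced genes were lower, with a median of -0.36 ± 0.14. Regular-diet replicate 1 lay below the regular-diet mean for the oxidation list (-0.20) and the gluconeogenesis list (-0.29). Of the 28 measured genes of oxidative phosphorylation, Cox5a fell (-0.37 ± 0.07) and 23 were lower, and 3 fell when adjusted over the list alone (adjusted p = 0.00148, and adjusted p = 0.580 with an estimated correlation). Without high-fat diet replicate 1 the last list was not shifted (adjusted p = 0.0774).

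Of the 17 measured acute-phase genes, 7 rose and all 17 were higher, with a median of 0.73, and 10 rose when adjusted over the list alone (adjusted p = 9.30e-15, and adjusted p = 0.206 with an estimated correlation). Beside Lcn2, Steap4 rose by 1.69 ± 0.13 (adjusted p = 0.00147), Saa4 by 1.42 ± 0.12 and Saa3 by 1.33 ± 0.19, and the assignment of signal between the similar serum amyloid A genes is uncertain. Of the 18 measured interferon-response genes, Gbp3 (0.86 ± 0.14, a lower bound) and Oasl2 (0.74 ± 0.13) rose and 17 were higher, and 13 rose when adjusted over the list alone (adjusted p = 5.66e-12, and adjusted p = 0.206 with an estimated correlation). Ifit1 had a log2 fold change of 1.55 ± 0.35 and did not pass (adjusted p = 0.0732), but passed without regular-diet replicate 1 (2.03, adjusted p = 0.00412). Relative to the regular-diet mean, the interferon list lay at 0.29 in that array, against -0.21 and -0.09 in regular-diet replicates 2 and 3. Of the 26 measured cytokine and chemokine genes, only Cxcl1, which encodes a neutrophil-attracting chemokine, rose (0.83 ± 0.09, adjusted p = 0.00687). Adjusted over the list alone, 3 rose and 1 fell (adjusted p = 0.00993, and adjusted p = 0.308 with an estimated correlation). This list was not shifted without regular-diet replicate 1 (adjusted p = 0.0922), without high-fat diet replicate 2 (adjusted p = 0.0870) or among the brighter genes (adjusted p = 0.0901). Tnf, Il6 and Ccl2, with log2 fold changes of 0.24, -0.17 and 0.68, did not pass (adjusted p = 0.325, 0.615 and 0.221).

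Among markers of other liver cells, 12 of the 14 measured markers of lipid-associated and recruited macrophages were higher, but the only member that changed over all genes was Cd9, which encodes a tetraspanin and fell (-0.74 ± 0.10, adjusted p = 0.0145). Adjusted over the list alone, 7 rose and 1 fell (adjusted p = 0.000921, and adjusted p = 0.308 with an estimated correlation). Several members lay near background: on the regular diet Mmp12, Itgax, Ly6c2, Atp6v0d2 and Gpnmb were under the median gene mean of 4.74 in every array. Itgax was under it in every high-fat diet array as well. Of the 18 measured markers of stellate cells and fibrosis, the collagen genes Col1a1 (0.85 ± 0.12, adjusted p = 0.0152) and Col3a1 (1.14 ± 0.14, adjusted p = 0.0115) rose, and 5 rose and 1 fell when adjusted over the list alone (adjusted p = 0.0048, and adjusted p = 0.233 with an estimated correlation). The median of the 16 other markers on that list was 0.13 ± 0.05. Neither the macrophage nor the stellate list was shifted among the brighter genes (adjusted p = 0.114 and 0.0901). The lists for Kupffer cells, lymphocytes, neutrophils, bile duct cells, hepatocytes, white adipose tissue and pancreas were not shifted, with adjusted p from 0.429 for hepatocytes to 0.873 for lymphocytes, and 0.467 for white adipose tissue. The neutrophil markers S100a8, Ly6g, Mmp8 and Mpo were under 4.74 in every array. So were the lymphocyte markers Cd3g, Cd4 and Gzmb and the pancreas markers Reg1 and Prss2, whereas Nkg7 and Ctrb1 were above it. For these lists the lack of a shift is therefore weak evidence that the cells did not differ. On the hepatocyte list Cps1, a urea cycle enzyme gene, fell (-0.66 ± 0.10, adjusted p = 0.0224). The endothelial list had an adjusted p of 0.0590 and 9 of 12 genes lower, and the 2 measured red blood cell markers were too few to test.

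Among genes of fat storage, Plin4 (1.38 ± 0.19), Fitm1 (1.25 ± 0.13) and Pparg (1.15 ± 0.20) rose while the lipid droplet gene Plin5 (-0.98 ± 0.13) and Fabp2 (-0.74 ± 0.09) fell. That list of 19 measured genes had 3 rises and 2 falls, or 4 and 3 adjusted over the list alone, and was not shifted (adjusted p = 0.320). Of the 20 measured genes of fatty acid and triglyceride synthesis, only Thrsp rose, 7 rose and 1 fell when adjusted over the list alone, and the list was not shifted (adjusted p = 0.0590). Fasn (0.87 ± 0.28, adjusted p = 0.207), Srebf1 (1.05 ± 0.26, adjusted p = 0.098), Scd1 (-0.43 ± 0.22, adjusted p = 0.439), Cd36 (1.27 ± 0.26, adjusted p = 0.0539) and Cidec (-0.58 ± 0.58, adjusted p = 0.742) did not pass. Cd36 passed without high-fat diet replicate 1 (1.52, adjusted p = 0.0444) and without extract replicate 2 (1.27, adjusted p = 0.0405), and Cidec stood at -1.29 without regular-diet replicate 1 (adjusted p = 0.191). Of the 17 measured genes of insulin signalling, Irs2, an insulin receptor substrate, fell (-0.95 ± 0.13, adjusted p = 0.0145), as did Igfbp2, and Pik3r1 rose (0.69 ± 0.13, adjusted p = 0.0369). That list was not shifted (adjusted p = 0.240), and 1 rose and 3 fell when adjusted over the list alone.

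Of the 18 measured genes of the unfolded protein response, none passed over all genes and 17 were higher, with Sel1l at 0.49 ± 0.10 (adjusted p = 0.0576, and 0.58 at an adjusted p of 0.0273 without regular-diet replicate 1), and 4 rose when adjusted over the list alone (adjusted p = 2.32e-05, and adjusted p = 0.308 with an estimated correlation). Of the 17 measured NRF2 and glutathione genes, Hmox1, the heme oxygenase 1 gene, rose (0.99 ± 0.18, adjusted p = 0.0345), and 4 rose when adjusted over the list alone (adjusted p = 0.00936, and adjusted p = 0.525 with an estimated correlation). Of the 21 measured drug-metabolising cytochromes P450, Cyp2c50 rose (0.78 ± 0.15, adjusted p = 0.0394), and 2 rose when adjusted over the list alone (adjusted p = 0.0267, and adjusted p = 0.709 with an estimated correlation). Cyp2b9, near background on the regular diet, had a difference of 5.43 ± 1.10 and did not pass (adjusted p = 0.0535), with high-fat diet replicate 1 at 6.52 against 11.37 and 10.41 in the others. It was 6.88 without that array, where it passed (adjusted p = 0.00914), and 4.46 without high-fat diet replicate 2 (adjusted p = 0.144), and it passed in 5 of 17 alternatives. Without high-fat diet replicate 2 neither the NRF2 list (adjusted p = 0.246) nor the P450 list (adjusted p = 0.653) was shifted, and the P450 list was not shifted without regular-diet replicate 3 (adjusted p = 0.0868). Abcc3 rose on the bile acid list (0.75 ± 0.12), which was not shifted (adjusted p = 0.156), and Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis, stood at -0.04 ± 0.44 (adjusted p = 0.983). The lists for lipid export, AMP-activated kinase, MHC class II, the circadian clock, male-biased and female-biased liver genes, the cell cycle and heat shock had adjusted p of 0.672, 0.429, 0.156, 0.701, 0.467, 0.888, 0.669 and 0.567. The female-biased list had a median of -0.09 but a mean of 0.32, and the lymphocyte list a median of -0.03 but a mean of 0.00. In total 12 of 32 lists were shifted, 9 upward and 3 downward, and none of these calls held with an estimated correlation, whereas fry called 5. Those were cholesterol synthesis and acute phase (adjusted p = 0.0103 each with fry) and interferon response, fatty acid oxidation and stellate cells (0.0205 each). Gluconeogenesis was not called with fry (adjusted p = 0.0974).

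**Figure D1:**
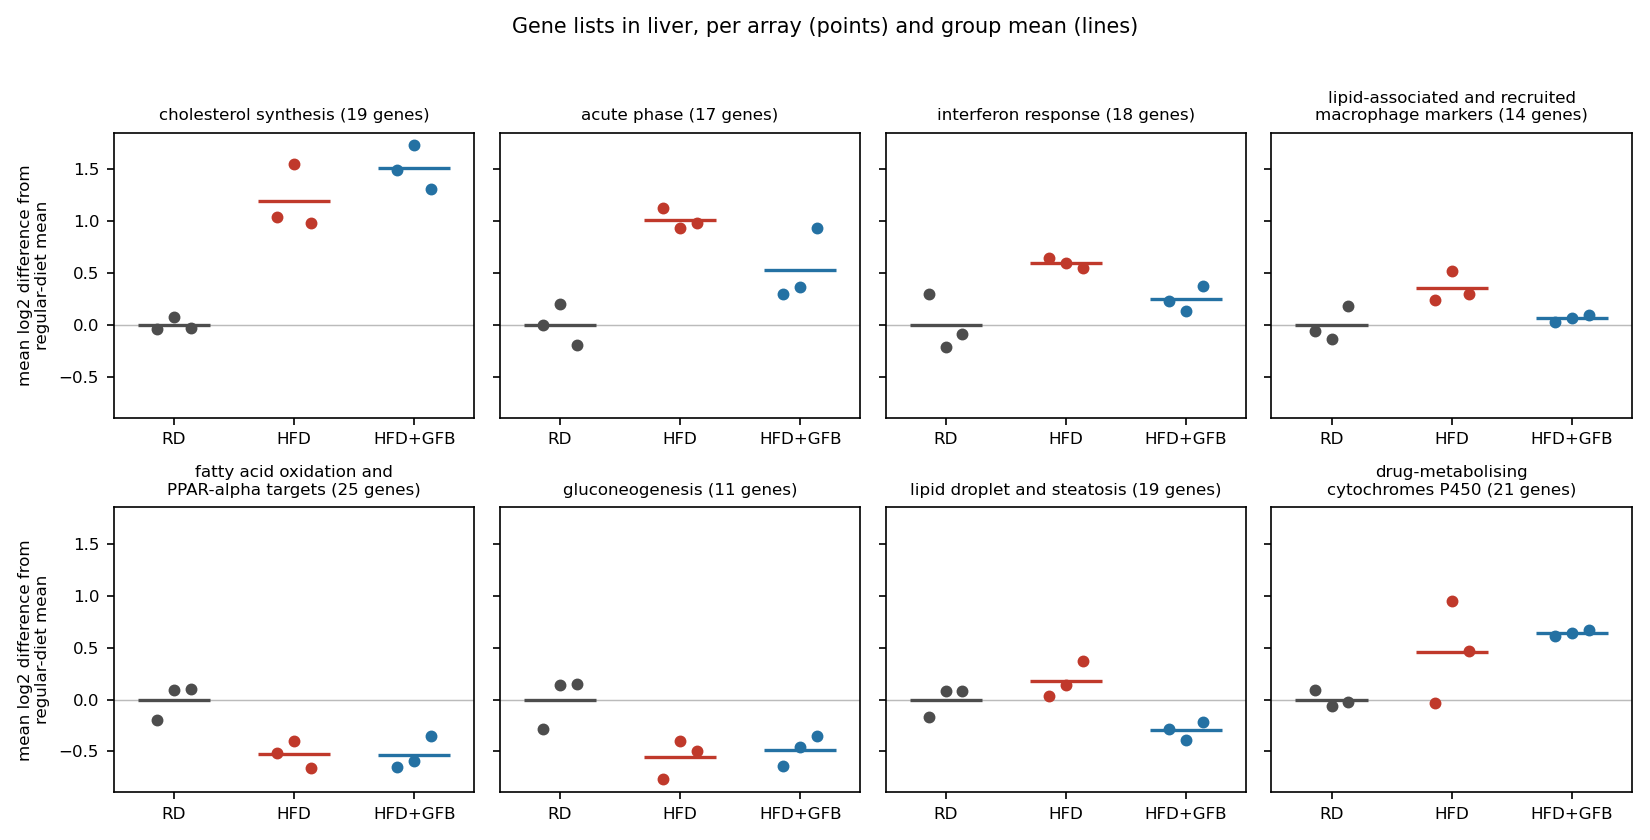
Mean log2 difference from the regular-diet mean (y axis) over the measured genes of 8 gene lists, with 1 point per array and a line at each group mean for the regular diet, the high-fat diet and the high-fat diet with extract (x axis). The cholesterol synthesis points lie between 0.98 and 1.56 on the high-fat diet and between 1.31 and 1.73 with extract, and the acute-phase points with extract lie at 0.30, 0.36 and 0.94.

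The extract was compared with the high-fat diet alone to describe its effect on that diet. Only Ces2a, which encodes a carboxylesterase, changed, and it rose 1.68-fold (0.75 ± 0.07, adjusted p = 0.0376). Its arrays lay at 9.76, 9.87 and 9.81 with extract and at 9.02, 9.16 and 9.02 without it, although near-identical carboxylesterase genes make the assignment of the signal uncertain. The 3 genes nearest the threshold among those that rose on the diet were lower with extract and did not pass, namely Col1a1 (-1.05 ± 0.12, adjusted p = 0.0851), Cxcl1 (-0.75 ± 0.09, adjusted p = 0.0851) and Col3a1 (-1.15 ± 0.14, adjusted p = 0.0975). Without high-fat diet replicate 1, Col1a1 (-1.19, adjusted p = 0.0112) and Col3a1 (-1.32, adjusted p = 0.0125) passed. Zfp982 (-1.08), Apoa4, an apolipoprotein gene (-1.12), Wsb1 (0.74), Ramp1 (0.49), Tmem47 (0.58) and Adgrl4 (0.49) came next, with adjusted p from 0.127 to 0.325. By limma, 1 of 22180 genes passed, while 1327 had an unadjusted p under 0.05 where chance gives 1109, and 9.69% of genes had no overlap between the groups, where chance gives 10%. The count was 0 without any 1 of regular-diet replicates 1 to 3, high-fat diet replicates 2 and 3 or extract replicates 1 to 3, and 3 without high-fat diet replicate 1. Ces2a was not among those 3, passed in 0 of 9 fits without 1 array, and had an adjusted p of up to 0.368 over the alternatives. The count was 4 among the brighter genes, 3 with array weights and 0 when only the 6 arrays compared were fitted.

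No member of any list passed over all genes in this comparison, so only values are given for single genes. All 18 measured interferon-response genes were lower with extract, with a median of -0.36, and 2 fell when adjusted over the list alone (adjusted p = 1.10e-09, and adjusted p = 0.227 with an estimated correlation). Gbp3 stood at -0.59 ± 0.14 and Oasl2 at -0.49 ± 0.13. Of the 19 lipid droplet genes, 17 were lower, with a median of -0.38, and 7 fell when adjusted over the list alone (adjusted p = 1.10e-09, and adjusted p = 0.181 with an estimated correlation). Among them were Plin4 (-0.89 ± 0.19), Plin2 (-0.55 ± 0.14), Fitm1 (-0.60 ± 0.13), Cd36 (-0.99 ± 0.26) and Cidec (-1.95 ± 0.58). Of the 14 markers of lipid-associated and recruited macrophages, 13 were lower, with Gpnmb, whose mean of 4.17 with extract is near background, at -0.80 ± 0.18, and 2 fell when adjusted over the list alone (adjusted p = 8.56e-07, and adjusted p = 0.227 with an estimated correlation). Of the 17 acute-phase genes, 13 were lower, with Lcn2 at -1.79 ± 0.35 and Saa3 at -1.09 ± 0.19, and 4 fell when adjusted over the list alone (adjusted p = 2.12e-05, and adjusted p = 0.312 with an estimated correlation). The mean shift of this list from the regular diet was 0.94 in extract replicate 3 against 0.30 and 0.36 in the other extract arrays.

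All 17 NRF2 and glutathione genes were lower with extract, with a median of -0.20 and none passing when adjusted over the list alone (adjusted p = 0.000191, and adjusted p = 0.312 with an estimated correlation). Of the 18 stellate and fibrosis markers, 11 were lower, and 5 fell and 1 rose when adjusted over the list alone (adjusted p = 0.00287, and adjusted p = 0.227 with an estimated correlation). Lrat, which encodes the retinol-esterifying enzyme of stellate cells, stood at 0.57 ± 0.12 while the collagens were lower. Cytokine genes were lower in 17 of 26 cases, with 1 fall adjusted over the list alone (adjusted p = 0.0130, and adjusted p = 0.312 with an estimated correlation). Genes of fatty acid and triglyceride synthesis were lower in 15 of 20 cases, with 1 fall adjusted over the list alone (adjusted p = 0.0179, and adjusted p = 0.516 with an estimated correlation). Fasn (0.04), Scd1 (-0.14), Srebf1 (-0.23), Cpt1a (-0.13), Tnf (-0.04), Il6 (0.23), Ccl2 (-0.40, near background with extract), Pparg (-0.58), Pck1 (0.18) and Cyp7a1 (0.42) did not pass, and Irs2 stood at 0.71 ± 0.13 (adjusted p = 0.325). Without high-fat diet replicate 2 the NRF2 list (adjusted p = 0.101), the cytokine list (adjusted p = 0.278) and the synthesis list (adjusted p = 0.475) were not shifted. The synthesis list was also not shifted without high-fat diet replicate 3 (adjusted p = 0.174) or extract replicate 3 (adjusted p = 0.238). The cytokine list was not shifted without extract replicate 1 (adjusted p = 0.0531) or among the brighter genes (adjusted p = 0.0779).

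All 19 genes of cholesterol synthesis were higher still with extract than on the high-fat diet alone, with a median of 0.30 and none passing when adjusted over the list alone (adjusted p = 8.56e-07, and adjusted p = 0.368 with an estimated correlation). Sqle stood at 0.71 ± 0.23, Stard4 at 0.70 ± 0.17 and Cyp51 at 0.65 ± 0.25. Endothelial markers were higher in 9 of 12 cases, with a median of 0.26, Clec4g at 0.56 ± 0.17 and Kdr at 0.42 ± 0.11, and 1 rose when adjusted over the list alone (adjusted p = 0.000134, and adjusted p = 0.384 with an estimated correlation). Cytochromes P450 were higher in 14 of 21 cases, with Cyp2c54 at 0.97 ± 0.18 and Cyp3a11 at 0.75 ± 0.22, and 3 rose when adjusted over the list alone (adjusted p = 0.00584, and adjusted p = 0.501 with an estimated correlation). The P450 list was not shifted without high-fat diet replicate 1 (adjusted p = 0.779) or extract replicate 3 (adjusted p = 0.0953). The circadian clock list was higher in 13 of 16 genes and the hepatocyte list in 9 of 12, both at an adjusted p of 0.0475, with none passing when adjusted over the list alone (adjusted p = 0.312 and 0.342 with an estimated correlation). The clock call was lost without regular-diet replicate 3 (adjusted p = 0.0622), high-fat diet replicates 2 (0.0534) and 3 (0.127), and extract replicates 2 (0.255) and 3 (0.0504). The hepatocyte call was lost without regular-diet replicate 2 (adjusted p = 0.0562), high-fat diet replicates 1 (0.265) and 2 (0.0534), and extract replicates 1 (0.0909) and 3 (0.126). Quantile normalization once more gave adjusted p = 0.0632 for the clock and 0.0791 for the hepatocyte list, and the brighter genes gave 0.195 for the clock. In total 13 of 32 lists were shifted, 5 upward and 8 downward, and none of these calls held with an estimated correlation or with fry. The lists not shifted had adjusted p from 0.0698 for insulin signalling to 0.990, and the gluconeogenesis list had a median of -0.02 but a mean of 0.07.

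**Figure D2:**
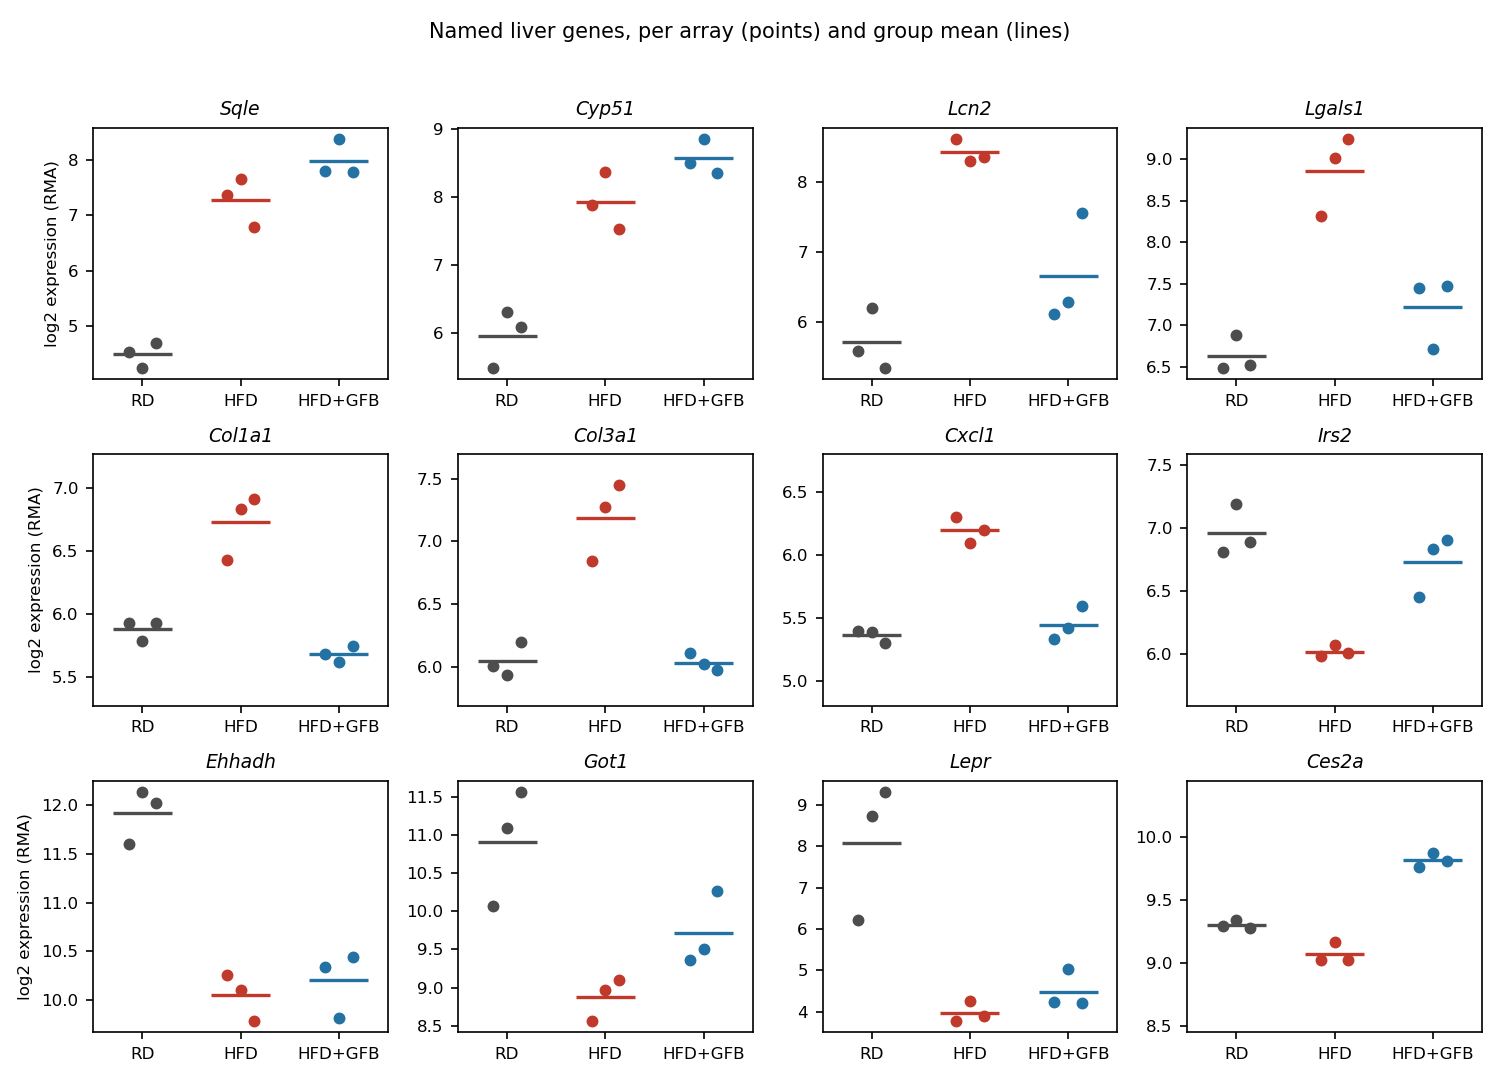
Log2 expression (RMA) of 12 genes (y axis, with its own range in each panel that does not start at 0) in the 9 arrays, with 1 point per array and a line at each group mean for the regular diet, the high-fat diet and the high-fat diet with extract (x axis). Col1a1 lies between 6.43 and 6.92 on the high-fat diet, between 5.79 and 5.93 on the regular diet and between 5.62 and 5.75 with extract, and Lepr on the regular diet lies at 6.23, 8.73 and 9.30.

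The extract group was also compared with the regular diet to describe what separated the extract-treated livers from livers on the regular diet. Of the named genes that passed, the 6 with the largest rises were on the cholesterol synthesis list. Sqle rose 11.2-fold (3.49 ± 0.23, adjusted p = 0.000941). Its regular-diet level lay near background, so apart from the spread between arrays this size is a lower bound. Msmo1 rose 8.09-fold (3.02 ± 0.29, adjusted p = 0.00783) and Cyp51 6.10-fold (2.61 ± 0.25, adjusted p = 0.00783), and Nsdhl, Fdps, Hmgcs1 and Insig1 rose by 1.93 to 2.39. Apoa4 fell 3.17-fold (-1.66 ± 0.16, adjusted p = 0.00783), Ehhadh 3.28-fold (-1.71 ± 0.20, adjusted p = 0.0140) and Acacb, which encodes the mitochondrial acetyl-CoA carboxylase, 1.85-fold (-0.88 ± 0.10, adjusted p = 0.0140). The transcription factor gene Foxq1 (2.07 ± 0.35), the deiodinase gene Dio1 (1.41 ± 0.23) and Saa4 (1.36 ± 0.12) also rose, although Foxq1 stood at 1.17 and did not pass with the mean of its probe sets (adjusted p = 0.0598). Cgref1, Rnu3a, Lamb3, Tmem86a, Cntnap1, Pgm3, Acot1 and Plin5 fell, with log2 fold changes between -1.72 and -1.01. In all, 98 genes changed, of which 58 rose and 40 fell, 36 of them by more than 2-fold. All 98 had no overlap between the groups, as did 14.6% of all genes, where chance gives 10%. The count was 15 and 18 without regular-diet replicates 2 and 3, 50 and 49 without high-fat diet replicates 1 and 3, and 3, 2 and 35 without extract replicates 1, 2 and 3. It was 267 without regular-diet replicate 1 and 34 when only the 6 arrays compared were fitted. Of the 27 named genes that passed, only Sqle passed without any 1 array.

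Of the 19 cholesterol synthesis genes, 14 rose, and all 19 rose when adjusted over the list alone, with a median of 1.13 (adjusted p = 3.31e-35, and adjusted p = 0.181 with an estimated correlation). Of the 25 genes of fatty acid oxidation, Ehhadh and Acot1 fell, and 14 fell when adjusted over the list alone, with a median of -0.43 (adjusted p = 1.00e-14, and adjusted p = 0.252 with an estimated correlation). Of the 17 acute-phase genes, Saa4 and Steap4 (1.03 ± 0.13) rose, and 5 rose when adjusted over the list alone (adjusted p = 2.51e-08, and adjusted p = 0.313 with an estimated correlation). None of the 11 gluconeogenesis genes passed, all 11 were lower, and 5 fell when adjusted over the list alone (adjusted p = 5.05e-06, and adjusted p = 0.332 with an estimated correlation). Of the 21 cytochromes P450, Cyp2c54 (1.26 ± 0.18) and Cyp2c50 (1.08 ± 0.15), which are near-identical paralogs, rose, and 8 rose when adjusted over the list alone (adjusted p = 5.93e-06, and adjusted p = 0.388 with an estimated correlation). Of the 19 lipid droplet genes, Plin5 (-1.01 ± 0.13) and Fabp2 (-0.91 ± 0.09) fell, and 2 rose and 5 fell when adjusted over the list alone (adjusted p = 0.0130, and adjusted p = 0.404 with an estimated correlation). Cidec stood at -2.53 ± 0.58 and did not pass (adjusted p = 0.127), nor did Fasn (0.92), Scd1 (-0.58), Srebf1 (0.82), Pparg (0.58), Cd36 (0.28), Cpt1a (-0.49), Tnf (0.20), Il6 (0.06), Ccl2 (0.28, near background in both groups), Pck1 (-0.71), Irs2 (-0.24) and Cyp7a1 (0.38). Cidec was -3.24 without regular-diet replicate 1, where it passed (adjusted p = 0.0158), and -1.94 without regular-diet replicate 3 (adjusted p = 0.253), and it also passed with the replicate block (adjusted p = 0.0394). The lipid droplet call was lost without regular-diet replicate 2 (adjusted p = 0.0552) and extract replicate 2 (adjusted p = 0.0841).

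No member passed over all genes on the lists for oxidative phosphorylation (median -0.13), the unfolded protein response (0.25), the interferon response (0.24), bile acids (0.18) and the circadian clock (0.13). Their adjusted p were 2.97e-05, 0.000207, 0.00474, 0.00558 and 0.0429, against adjusted p of 0.414, 0.388, 0.594, 0.215 and 0.322 with an estimated correlation. Adjusted over the list alone, 4 oxidative phosphorylation genes fell, 2 bile acid genes rose and 1 fell, and none of the others passed. The interferon call was lost without regular-diet replicate 2 (adjusted p = 0.281) and extract replicate 3 (adjusted p = 0.144). The clock call was lost without regular-diet replicates 1 (adjusted p = 0.351) and 3 (0.0682), high-fat diet replicate 3 (0.0550) and extract replicate 2 (0.153), among the brighter genes (0.0949) and after quantile normalization once more (0.0503). The lipid export list was not shifted (adjusted p = 0.751), although Apoa4 and Apoc2 (-0.60 ± 0.07) fell, 2 of 17 genes over all genes and adjusted over the list alone. In total 11 of 32 lists were shifted, 7 upward and 4 downward, none held with an estimated correlation, and fry called 4. The lists not shifted had adjusted p from 0.314 to 0.996. Medians and means differed in sign for the insulin signalling, AMP-activated kinase, NRF2, Kupffer, macrophage, cell cycle, hepatocyte and white adipose lists, none of them shifted.

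Of the 98 genes that separated extract-treated livers from the regular diet, 72 had also changed with the high-fat diet in the same direction (47 rose, 25 fell) and 0 in the opposite direction. If the sets were independent, 0.476 and 0.207 would be shared, but both comparisons hold the regular-diet arrays. The effects correlated across genes at 0.750 (covariance 0.0365), and genes are not independent replicates. Simulated unchanged groups that share those arrays gave a mean of 0.496 (covariance 0.0106). With the extremes at both ends set aside, their correlations ran from -0.195 to 0.894, which includes 0.750. Their covariances ran from -0.00243 to 0.0303 on the same terms, below 0.0365. Of the 297 genes changed by the diet, 252 (84.8%) had the opposite sign with extract, 155 of the 182 that rose and 97 of the 115 that fell. The high-fat diet arrays enter the diet and extract effects with opposite signs, and simulated unchanged groups sharing them gave a mean of 80.4%. The simulated shares ran from 28.2% to 100% with the extremes at both ends set aside. Those groups hold no diet effect, so 84.8% beside 80.4% cannot decide whether the extract had an effect. The covariance of the diet and extract effects was -0.0155 (correlation -0.433), against a mean of -0.0102 (correlation -0.455) in the simulated groups. Both observed values lay within the simulated ranges, -0.0367 to 0.00233 (correlation -0.910 to 0.194) with the extremes set aside. With a different high-fat diet array set aside in turn as the only reference for extract, 64.9%, 76.1% and 68.3% of the diet calls had the opposite sign, and the covariance had a mean of -0.00561. Among 100 simulations with the measured diet effect and no extract effect, 25 gave a covariance as low and 6 a least share as high as 64.9%. The median log2 fold change against the regular diet of the genes that rose with the diet was 0.71 without and 0.47 with extract, and of those that fell -0.56 and -0.40, on genes chosen for their change on the diet. Across the 3 groups, 173 genes differed by limma's moderated F test, from 12 without regular-diet replicate 2 to 305 without regular-diet replicate 1. The count was 26 without regular-diet replicate 3, 74, 68 and 30 without high-fat diet replicates 1 to 3, and 52, 40 and 74 without extract replicates 1 to 3.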

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

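The tests of the 3 patterns weighed here were chosen after the results were seen, while the splits of the arrays into other groups were planned before their counts were seen. Signal outside the genes tested drew attention in the comparison of the high-fat diet with the regular diet. Of the 16010 probe sets without a gene in the annotation table, 1 was higher and 1 lower on the high-fat diet at an adjusted p under 0.05, and 1224 had an unadjusted p under 0.05. Of the 1814 probe sets paired with several genes, 9 were higher and 15 lower, and 218 had an unadjusted p under 0.05. With extract against the high-fat diet, limma called 0 of either kind, with 683 and 85 at an unadjusted p under 0.05.

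Other splits of the arrays were fitted in the same way. Each comparison of 3 arrays with 3 has 10 splits, which are too few for a share under 0.05. The real split gave 297, 1 and 98 genes for the diet, the extract and the extract group against the regular diet, and the highest of the other splits gave 0 in each, so 1 of 10 splits reached the real count in each. For gene lists the real split gave 12, 13 and 11, the highest other split gave 11, 14 and 10, and 1, 2 and 1 of 10 splits reached the real count. The preset-correlation list test therefore called many lists in splits that mix the groups, and its counts alone say little about the groups. Of 100 splits of the 9 arrays into 3 groups, only the real one reached the 173 genes of the F test, and the highest other gave 105. A share under 0.05 argues against chance if the arrays are independent samples, which the labels do not state.

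Genes changed by the high-fat diet lay on the opposite side with extract in 84.8% of cases. A single deviating high-fat diet array stays open: with each of the 3 arrays in turn as the only reference for extract the least share on the opposite side was 64.9%, and 6 of 100 simulations without an extract effect gave a least share as high. The sharing of the high-fat diet arrays is by itself expected to give the diet and extract effects a covariance of -0.0103, against -0.0155 observed. Whether it accounts for all of the observed value stays open: 22 of 100 simulations with the measured diet effect and no extract effect gave a covariance as low. With separate high-fat diet arrays for the diet and extract effects the covariance was -0.00561, and 25 of 100 simulations without an extract effect were as low. A partial offset of the diet by the extract, the biological explanation the design gives, therefore did not stand out from chance in these tests and stays open.

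Col1a1 and Col3a1 rose with the high-fat diet and were lower with extract, near their regular-diet levels. More stromal tissue in the high-fat diet samples stays open. The median of the 16 other measured stellate markers was 0.135 (standard error 0.0515) against a mean of 0.994 (standard error 0.0938) for the collagens. The collagens were picked because they alone on that list passed, so a lower median of the other markers follows from the choice and cannot decide the question. The change of the collagens with extract ranged from -1.32 to -0.950 when each high-fat diet or extract array was left out. No single array therefore carried the change of these genes. They were picked for small p-values, which favours genes whose arrays lie close together within a group. That result follows in part from the choice and does not decide whether an array deviates for other genes. A higher collagen output per stellate cell on the diet, and less of it with extract, are possible explanations that were not tested.

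Most genes of fatty acid oxidation and gluconeogenesis were lower and those of cholesterol synthesis higher on the high-fat diet, with 4 of 25, 1 of 11 and 12 of 19 passing singly and no list shifted with an estimated correlation (adjusted p = 0.236, 0.308 and 0.206). Livers collected at another time of day stay open, since evening clock genes minus morning clock genes differed by 0.192 with a 95% interval from -0.958 to 1.34. A shorter or weaker fast stays open as well: 7 of 7 measured fasting-induced genes were lower, with a median of -0.364 (standard error 0.145), which lies between the values set for and against it. Regular-diet replicate 1 lay nearer the high-fat diet arrays for Lepr, Got1 and the oxidation and gluconeogenesis lists, as different fasting states among the regular-diet samples might give. It also lay nearer them on the interferon list (0.29 against -0.21 and -0.09 in regular-diet replicates 2 and 3). The same held on the first principal component (-10.79 against -23.06 and -26.63). On the cholesterol synthesis list it did not (-0.04 against 0.07 and -0.03). This array thus stood apart more broadly, for a cause not tested. The diet itself, the biological explanation in the design, cannot be told apart from these with the arrays at hand.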

How the results depend on the processing

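All alternatives but the separate high-fat diet arrays for the diet and extract effects were planned. The named genes that passed numbered 44, 1 and 27 for the diet, the extract and the extract group against the regular diet. Under the alternatives 0 of them changed sign. The arrays of the compared groups did not overlap for any called gene, so leaving out an array could not change a sign. The absence of sign changes is therefore little evidence of stability. Calls were not stable: 7, 0 and 1 of these genes passed under every alternative. Against 297, 1, 98 and, for the F test, 173 genes, the brighter genes gave 597, 4, 232 and 396, where fewer genes were tested, and an adjusted p under 0.10 gave 611, 4, 216 and 381. Fits of only the 6 arrays compared, with fewer arrays for the variance, gave 15, 0 and 34 genes. A fold change of at least 1.5 left 171 diet genes, array weights gave 3 extract genes and the variance trend with robust moderation 275 in the F test, and these causes were not tested. Leaving out 1 array gave 58 to 452, 0 to 3, 2 to 267 and 12 to 305 genes. Lists numbered 12, 13 and 11, and 11 to 14, 9 to 15 and 9 to 11 without 1 array, but 0, 0 and 0 with an estimated correlation and 5, 0 and 4 with fry. The covariance of the diet and extract effects was -0.0155, from -0.0217 without high-fat diet replicate 1 to -0.0146 without regular-diet replicate 1, and -0.00561 with separate high-fat diet arrays. Some uncalled genes changed sign without 1 array, for causes not tested. Cidec ranged from -1.29 to 0.0082 on the diet, Cyp7a1 from -0.42 to 0.43 on the diet and from -0.048 to 0.75 with extract, and Pck1 from -0.14 to 0.46 with extract. Dim genes such as Il6 lie near background, which limits what their values can show.

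With the replicate number as a block, 201, 1, 68 and, for the F test, 82 genes passed, and 13, 14 and 11 lists. The extract gene was a different one (0 shared). Correlations of same-numbered arrays about their group means ran from -0.0511 to 0.173 and 3 of 9 arrays correlated best with their own number, so the numbers give no sign of a pairing.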

Other observations

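The gene families in this part were chosen after their values were seen, so their tests describe the data and need other samples. On the high-fat diet 12 of 63 measured ribosomal protein genes fell and none rose, with a median of -0.21 (-0.19 after quantile normalization once more and -0.22 with each array shifted to the same median). Among them were Rps3a1 (-0.57 ± 0.07) and Rpl7 (-0.55 ± 0.06). Of 73 small nucleolar RNAs with Snora or Snord symbols, many of which lie in introns of genes for the translation machinery, 15 fell and none rose, with a median of -0.41, and -0.41 and -0.42 under the same rescalings. The near-identical copies Snora73b and Snora73a were among them, with Snora73a at -1.48 ± 0.22. Of 483 microRNA genes on the same arrays none passed, 280 were lower and 203 higher. Camera with an estimated correlation was adjusted over 18 tests of 6 families in 3 comparisons. It gave adjusted p = 0.0401 for the ribosomal proteins, 0.0401 for the small nucleolar RNAs and 0.0543 for the microRNA genes. With extract none of either family passed, and their medians were 0.09 and 0.08 (adjusted p = 0.109 and 0.388). In the extract group against the regular diet 4 small nucleolar RNAs fell and 69 of 73 were lower, with a median of -0.34 (adjusted p = 0.0453), and no ribosomal protein gene passed, with a median of -0.12 (adjusted p = 0.0509).

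Of 52 measured genes of amino acid breakdown and the urea cycle, 11 fell on the high-fat diet and only Agxt2 rose (0.75 ± 0.12). The falls spanned Got1, Csad, Cth, Acmsd (-1.01 ± 0.19), Asl (-0.96 ± 0.18), Hal (-0.76 ± 0.14), Aass (-0.72 ± 0.10), Hgd (-0.69 ± 0.12), Slc25a15 (-0.69 ± 0.11), Cps1 (-0.66 ± 0.10) and Arg1 (-0.59 ± 0.10). The share of falls exceeded that of other genes (two-sided Fisher's exact test, p = 2.26e-15 and adjusted p = 1.35e-14, which treats genes as independent), while camera with an estimated correlation gave adjusted p = 0.211. Of 19 carboxylesterase genes 4 rose on the diet (Ces1g, Ces2e, Ces2g and Ces3a; adjusted p = 0.0467 with an estimated correlation), and the member that rose with extract, Ces2a, stood at -0.23 on the diet (adjusted p = 0.170). All 10 guanylate-binding protein genes were higher on the diet, of which Gbp10, Gbp3 and Gbp7 rose (adjusted p = 0.0401 with an estimated correlation), and 9 of 10 were lower with extract (adjusted p = 0.0467).

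Sex-biased liver genes differed widely between the 3 high-fat diet arrays, and neither list was shifted in any comparison. Relative to the regular-diet mean, the male-biased list lay at 1.00, -0.48 and 0.25 in high-fat diet replicates 1, 2 and 3, and the female-biased list at -0.26, 0.81 and 0.41. Cyp2b9 lay at 6.52, 11.37 and 10.41 in the same arrays, against 5.00, 3.47 and 3.56 on the regular diet. It is among the 13 measured genes of the female-biased list, so it adds to the values of that list and is not separate support for them.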
